A study of Rattus norvegicus with 16 samples.

How the data were processed

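Messenger RNA levels were measured in NG108 cells, a line that the labels call rat neuronal and that is known as a hybrid of mouse neuroblastoma and rat glioma cells. Per the labels, 8 samples were exposed to 0.25% dimethyl sulfoxide (DMSO) as the control and 8 to 4400 ng/ml of mefloquine, an antimalarial drug with known neurological side effects, each for 2 hours. Total RNA was extracted with RNA STAT-60 reagent, and 10 µg was hybridised to each Affymetrix rat array, per the labels. The deposited values are intensities on a linear scale, 1 column per array, which the authors scaled with the standard chip scaling factors and did not transform further, per the labels. The scanner software, its version and the target intensity are not given in the sources used here. The table held 1031 probe sets, of which 59 were control probe sets, and 26.9% of the values were at or below 0, as occurs when mismatch signal is subtracted from perfect-match signal.

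Groups and replicate numbers came from the sample titles. The titles number the samples 1 to 8 in each group, but nothing in the labels says that they came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical. Whether the mefloquine samples also contained DMSO is not stated in the labels used here. At most 0.1% of the values were identical between any 2 arrays. The number of arrays, 8 per group, limits the precision.

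Of the 972 probe sets for genes, 821 carried exactly 1 gene symbol in the platform annotation, together naming 549 genes, while 38 carried several symbols and 113 carried none. No symbol needed updating through its Entrez identifier against the RefSeq gene table, and 10 symbols were not found in that table. Probe sets with several symbols were tested but not named. No genome build is tied to the table, so no coordinates are given.

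The following choices were made before the data were examined. Values below a floor, the 25th percentile of all positive values over the 16 arrays (426.5 intensity units), were set to that floor, and log2 was taken. Fold changes are thus on a floored scale, which can understate the change of dim probe sets, and are ratios of geometric means, while intensities are given as arithmetic means. Probe sets above the floor on at least 8 of the 16 arrays, counted without regard to group, were tested, which left 545 probe sets and 342 singly named genes. The model had treatment as its only term and was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). A probe set was called changed at a Benjamini-Hochberg adjusted p under 0.05. Single values were compared by exact permutation tests over all 12870 divisions of the arrays into 8 and 8, two-sided unless stated.

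There were 26 gene lists, fixed in advance for drug stress, signalling, neuronal and glial functions. Each gene entered by its brightest probe set. Lists with at least 3 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and fry as alternatives. Only 10 lists had enough tested genes, and 8 lists had no probe set on this array, among them the lists for glutamate, GABA and acetylcholine receptors, synaptic vesicles and neuronal markers. The named genes were, by rule, up to 12 genes with the largest increase and 12 with the largest decrease among called probe sets with 1 symbol, given that at least 7 of 8 treated arrays lay on that side of the DMSO mean, plus up to 4 members of each list with the smallest p. Probe sets without a symbol were named by identifier, at most 2 in each direction.

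Alternatives were quantile normalization, division of each array by its median positive value, floors at the 10th and 40th percentile, an offset in place of the floor, no filter, a filter requiring all 16 arrays above the floor, eBayes with trend and robust settings, array quality weights, the replicate number as a block, the GAPDH 3' over 5' ratio as a covariate, and each array left out in turn. Added after the data had been seen were a block for replicates 1 to 5 against 6 to 8 (also with array weights), each of those ranges alone, the fit without the 3 arrays that stood apart, the immediate early list without Jun and with an estimated correlation under the settings that called it, and 4 further gene lists, of which the respiratory chain was also tested without arrays that stood apart. The difference between the ranges was also counted with RNA quality ratios or spike-ins as covariates, on all arrays and with arrays left out, and within each group. The array separation was also tested against divisions within the ranges. On all arrays, the first form of the count between the ranges, 97 probe sets differed with the GAPDH ratio as a covariate. DMSO control 3 dominates that ratio, so the count without the 3 arrays was used instead. A first test of a shared condition, the correlation between the groups of the difference between the ranges (0.718, and 0.746 without the 3 arrays), was dropped as a test because the ranges had been noticed on the same arrays of both groups. Its replacement chose 3 numbers from the DMSO arrays alone and ranked them in the mefloquine arrays, but it was also set after these arrays had been seen.

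The fit was tested on simulated data with the 545 probe sets and 8 arrays per group, in 20 runs with 60 changed probe sets each. It recovered 37.5% of the changes of 0.5 on the log2 scale, 81.5% of those of 1 and 97.2% of those of 2, and 4.01% of its calls were false. The simulated noise was independent and normally distributed, with no floor and no structure between arrays. With 60 changed probe sets the adjusted threshold is also more lenient than with the 7 called here. These shares may therefore overstate what could be found in the real data. The list test was run 50 times with independent noise on 1 list of 10 genes, all raised by 1 on the log2 scale. At an unadjusted p under 0.05 it called 100% of these shifted lists and 0% of unshifted ones. Smaller shifts, genes that vary together and adjustment over several lists were not simulated. The 100% therefore does not say how often the real lists could have passed.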

Results

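The transcript levels of NG108 neuronal cells were measured on 16 arrays, 8 from cells given DMSO and 8 from cells given 4400 ng/ml mefloquine, after 2 hours. The arrays had median intensities for gene probe sets between 461 and 665, and between 495 and 552 of the 972 gene probe sets lay above the floor on each. The probes are for rat sequences, while the cells are known as a mouse and rat hybrid. How well mouse transcripts are measured was not tested here, so an unchanged or dim value does not exclude a change in them. The comparison asks which transcripts differ between drug-treated and control cells after this short exposure.

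The transcripts of 3 named genes were higher in mefloquine cells. Ddit3, which encodes the stress-induced transcription factor CHOP, rose 4.66-fold, from an intensity of 692 ± 429 in DMSO cells to 3159 ± 1026 in mefloquine cells (SD, n = 8 each). Jun, a subunit of the AP-1 transcription factor, rose 3.55-fold, from 1600 ± 592 to 5707 ± 2513 (SD, n = 8 each). Nfkbia, the inhibitor that holds NF-kappa-B in the cytoplasm, rose 2.71-fold, from 2708 ± 516 to 7659 ± 2725 (SD, n = 8 each). By the brightest probe set of each gene, all 8 mefloquine arrays lay above the highest DMSO array.

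On the log2 scale the differences were 2.22 ± 0.26 (SE) for Ddit3, 1.83 ± 0.29 for Jun and 1.44 ± 0.21 for Nfkbia. Their adjusted p-values in limma were 9.28e-05, 0.0012 and 0.00057. The exact permutation p was 0.000155 for each gene, which is the smallest that 8 against 8 arrays can give. Ddit3 was at the floor on 2 DMSO arrays. The other probe sets of these genes moved the same way: Jun rose 2.16-fold and 2.20-fold by its dimmer probe sets, each with a limma adjusted p of 0.0425, and Nfkbia rose 2.26-fold by its other probe set, with a limma adjusted p of 0.0037. By each of these dimmer probe sets 6 of 8 mefloquine arrays lay above the highest DMSO array, and the dimmest Jun probe set was at the floor on 5 DMSO arrays. When 1 array at a time was left out, the calls of Ddit3, Nfkbia and the brightest Jun probe set held in all 16 fits. The dimmer Jun probe sets passed only without DMSO control 1 or 3 or mefloquine 7 or 8 for rc_AA945867_at, and without DMSO control 4 or mefloquine 5 or 8 for X17163cds_s_at, with limma adjusted p-values up to 0.109 and 0.114.

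**Figure D1:**
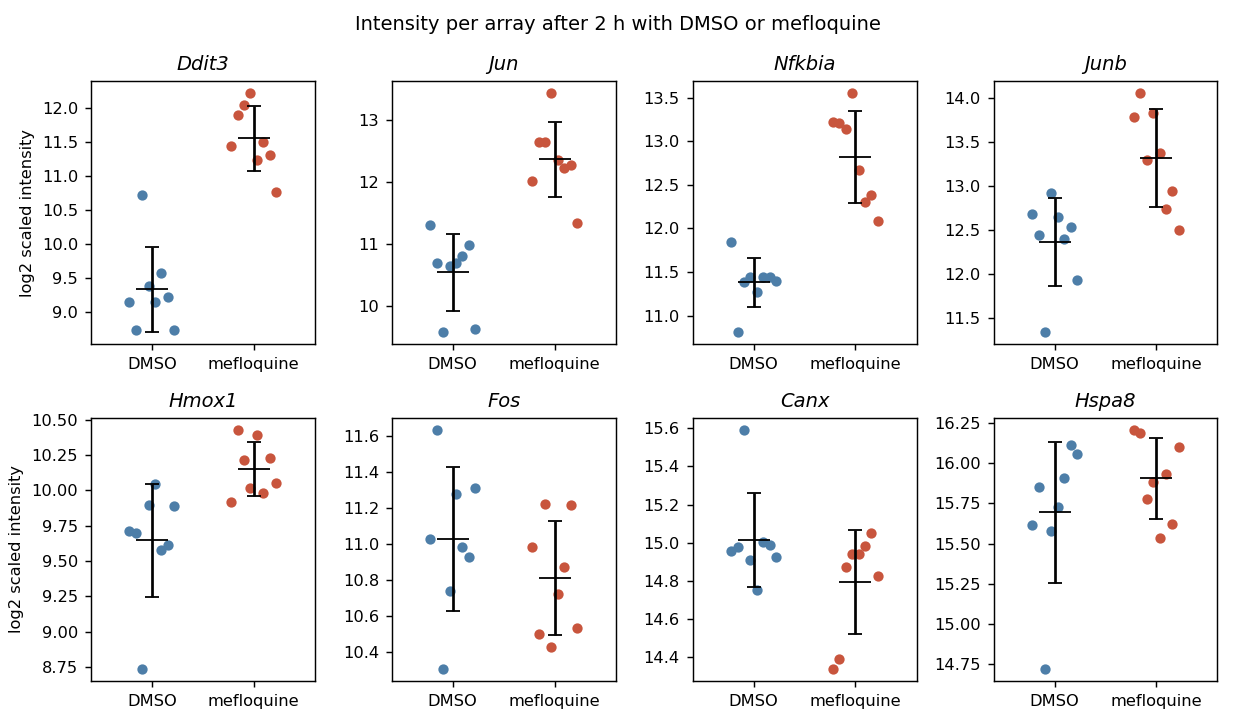
Log2 scaled intensity (vertical axes, each with its own range) of 8 genes on each array, with DMSO control arrays in blue and mefloquine arrays in red; black lines give the mean and SD of 8 arrays. The mefloquine points of Ddit3, Jun and Nfkbia all lie above the DMSO points, while those of Junb, Hmox1, Fos, Canx and Hspa8 overlap them.

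In all, 7 of the 545 tested probe sets passed limma's test with Benjamini-Hochberg adjustment, 6 higher and 1 lower with mefloquine, and 6 of them changed at least 2-fold. The 6 that rose belonged to Ddit3, Jun and Nfkbia. The probe set that fell, AA956437_at, has no gene symbol in the annotation used here. It went from 717 ± 318 to 466 ± 64.9 (SD, n = 8 each), a log2 difference of -0.68 ± 0.15 (SE) with a limma adjusted p of 0.026, close to the floor. Its call was lost without DMSO control 2, 4, 6, 7 or 8 or mefloquine 3, 4, 5 or 7. With 1 array left out at a time, its limma adjusted p ranged from 0.000135 to 0.0733. The call held without DMSO control 3, where this probe set was at the floor, and without that array and mefloquine 1 and 2. The count of called probe sets was 4 without DMSO control 2, 6, 7 or 8 or mefloquine 3 or 4. At an unadjusted p under 0.05 there were 23 probe sets, 13 higher and 10 lower, against 27.2 expected by chance. That limma count depended on the arrays and the model. It was 44 without DMSO control 3, 47 with the GAPDH ratio as a covariate and 42 with the replicate range as a block and array weights. Without mefloquine 1 it was 17. The median difference over all tested probe sets was -0.01 on the log2 scale, and for 478 of them (87.7%) the 95% interval excluded a 2-fold change in either direction.

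The arrays with replicate numbers 6 to 8 differed from those numbered 1 to 5 by 68 probe sets over both groups together. Within DMSO arrays alone 19 probe sets differed and within mefloquine arrays alone 41, for ranges that were noticed on these arrays. Without DMSO control 3 and mefloquine 1 and 2, which stood apart, 48 differed within DMSO arrays (n = 3 and 4). Within mefloquine arrays 40 then differed (n = 3 and 3), so the order of the groups rests on these arrays. Within replicates 1 to 5 the log2 differences were 2.34 for Ddit3, 2.04 for Jun and 1.80 for Nfkbia, and all 3 passed. Within replicates 6 to 8 they were 2.02, 1.47 and 0.83 and none of these passed (limma adjusted p of 0.0605, 0.415 and 0.0642, with 3 arrays per group), while the other Nfkbia probe set passed in both ranges, with log2 differences of 1.18 and 1.17. In limma's test of whether the treatment effect differed between the ranges, 0 probe sets passed and 23 had an unadjusted p under 0.05.

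Of the 10 tested members of the endoplasmic reticulum stress and unfolded protein response list, 1 rose (Ddit3) and 9 did not pass, and the count was the same when adjusted over the list alone. The other genes of the 27 in this list, among them Atf4, Atf3 and Trib3, had no probe set of their own here. The chaperone Canx differed by -0.22 ± 0.14 (log2, SE), and the disulfide isomerases Pdia3 and Pdia6 by -0.26 ± 0.24 and -0.15 ± 0.13. Without the 3 arrays that stood apart (DMSO control 3 and mefloquine 1 and 2) Canx was at 0.01, Pdia3 at -0.04 and Pdia6 at 0.02, and of the 4 other Canx probe sets 2 were above 0. Hspa5, the main chaperone of the compartment, named after its values were seen, differed by -0.05 with a 95% interval from -0.31 to 0.21. As a list it did not pass camera (limma, adjusted p = 0.516; p = 0.273 with an estimated correlation), and its median of -0.01 and mean of 0.23 differed in sign. DMSO control 3, the array with the highest 3' over 5' ratios, had the highest Ddit3 and Canx values among the DMSO arrays.

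The immediate early list, of genes that respond to stimuli without new protein synthesis, held 40 genes, with 8 on the array and 5 tested. Of these 5, 1 rose (Jun), and 2 rose when adjusted over the list alone (Jun and Junb). Junb, another AP-1 subunit, was 1.93-fold higher, from 5531 ± 1622 to 10863 ± 4024 (SD, n = 8 each), with a limma adjusted p of 0.0981 over all probe sets. It passed with the replicate range as a block (0.0364), and over all alternatives its adjusted p ranged from 0.0282 to 0.691. Its log2 difference was 1.26 in replicates 1 to 5 and 0.44 in replicates 6 to 8. Fos, the usual partner of Jun, differed by -0.22 ± 0.18 (log2, SE) and the inducible cyclooxygenase gene Ptgs2 by -0.25 ± 0.15. The list's camera p was 0.0231 (limma, adjusted p = 0.231; p = 0.145 with an estimated correlation). Its median was -0.02 and its mean 0.46. At the preset correlation it passed under 3 alternatives, with a floor at the 40th percentile (adjusted p = 0.0147), with all 16 arrays above the floor (0.00533) and with all probe sets of its members (0.000258), against a range of 0.000258 to 0.861 over all alternatives. With an estimated correlation none of these 3 calls held (adjusted p = 0.337, 0.19 and 0.105), and the last counts 3 Jun probe sets. Without Jun the list passed neither in the main setting (adjusted p = 0.861) nor under these 3 (0.687, 0.642 and 0.786).

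No member of the heat shock, oxidative stress, growth factor, cytokine, apoptosis, MAP kinase, cell cycle or cholesterol lists passed limma's test, either over all probe sets or adjusted over the list alone. Values of genes that did not pass are given as description: of the 51 named genes, 39 (1 of them called, Nfkbia) moved by over 1.5 times or turned in sign within replicates 1 to 5 or 6 to 8, and 37 (0 called) when 1 array was left out. Of the 20 with other tested probe sets, 6 had at least 1 in the opposite direction, none of them called. Of 11 heat shock and chaperone genes, the constitutive chaperone Hspa8 differed by 0.21 ± 0.18 (log2, SE), Dnaja1 by -0.18 ± 0.13 and Hspd1 by -0.13 ± 0.13. Without the 3 arrays that stood apart Hspa8 was at -0.03 and Hspd1 at 0.02, and Dnaja1 was at 0.06 in replicates 6 to 8 alone. On DMSO control 3, Hspa8 was the lowest and Hspd1 the highest of the DMSO values. Of 12 oxidative stress genes, heme oxygenase Hmox1 was 1.42-fold higher (773 ± 324 against 1148 ± 155, SD, n = 8 each; limma adjusted p = 0.266), with all 8 mefloquine arrays above the DMSO mean, and the quinone reductase Nqo1 differed by -0.34 ± 0.19 (-0.18 in replicates 1 to 5 and -0.61 in replicates 6 to 8). DMSO control 3 also had the lowest Hmox1 value.

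Of 15 genes of the MAP kinase pathway, the ERK phosphatase Dusp6 differed by -0.94 ± 0.38 (log2, SE; limma adjusted p = 0.821), with mefloquine 1 and 2, which stood apart in other measures, at the floor. Its difference was -1.32 in replicates 1 to 5 and -0.30 in replicates 6 to 8. The kinase Mapk7 differed by -0.35 ± 0.20 (-0.12 in replicates 1 to 5 and -0.75 in replicates 6 to 8). Of 7 apoptosis genes, the survival factor Bcl2l1 differed by 0.45 ± 0.27 by its brightest probe set (0.86 in replicates 1 to 5 and -0.24 in replicates 6 to 8) and by -0.33, -0.32 and 0.01 by the others, and the death effector Bax by -0.03 ± 0.10 (0.20 in replicates 6 to 8). Of 9 cell cycle genes, cyclin D1 (Ccnd1) differed by 0.40 ± 0.18 (limma adjusted p = 0.982) and Pcna by 0.17 ± 0.17, with the other probe set of each at 0.03 and -0.00. Of 9 growth factor and receptor genes, Tgfbr3 differed by -0.35 ± 0.16 (0.07 by its other probe set) and Vegfa by 0.22 ± 0.36. The Vegfa value averages opposite differences, 0.96 in replicates 1 to 5 and -1.01 in replicates 6 to 8. In limma's test of whether the treatment effect differed between the ranges, Vegfa did not pass (adjusted p = 0.839). Of 8 cytokine genes, Il1rap differed by 0.35 ± 0.19 (0.52 in replicates 1 to 5 and 0.06 in replicates 6 to 8) and Il15 by -0.18 ± 0.13. The 3 cholesterol and lipid genes Cyp51, Dhcr7 and Scd differed by 0.16 ± 0.29, 0.14 ± 0.10 and 0.12 ± 0.27, and without DMSO control 3, where Cyp51 was far below the other DMSO arrays, Cyp51 was at -0.12 and Scd at -0.01. The other Cyp51 probe sets were at -0.15, 0.22 and 0.03.

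None of the 10 tested lists passed limma's camera at the preset correlation, with an estimated correlation or by fry. At an unadjusted p under 0.05, camera at the preset correlation gave the immediate early list. Lists with fewer than 3 tested genes were not tested as lists. Their measured members also did not pass: the glial markers Vim and Clu differed by -0.08 ± 0.12 and -0.32 ± 0.21 (log2, SE), monoamine oxidase Maoa by -0.28 ± 0.19, the somatostatin receptor Sstr4 by -0.02 ± 0.20 and the potassium channel Kcnj8 by -0.07 ± 0.17. Vim was at 0.07 in replicates 6 to 8 alone, and Sstr4 at 0.11 without DMSO control 2.

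**Figure D2:**
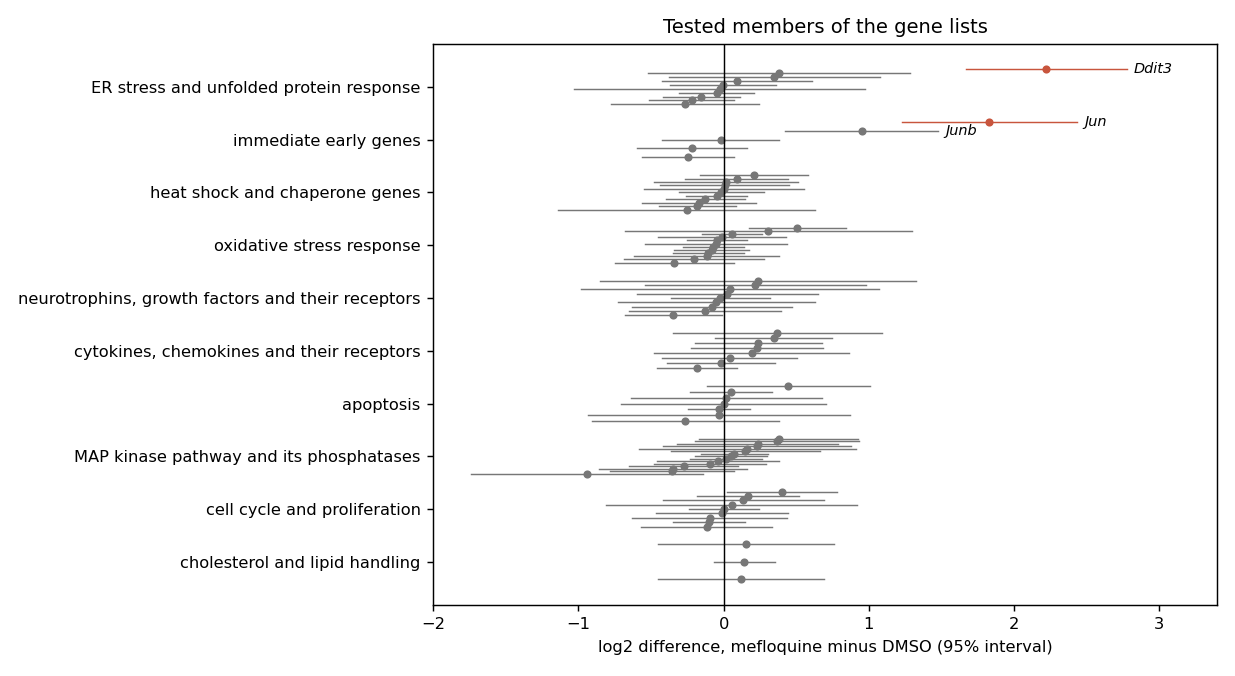
Log2 difference, mefloquine minus DMSO, of each tested gene (points) with its 95% interval (lines), grouped by the 10 tested gene lists; ER stands for endoplasmic reticulum. Red marks the genes that passed limma's test over all probe sets, Ddit3 and Jun, and Junb is named as the gene that passed over its list alone.

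As a whole, the arrays were not separated by treatment in the planned test, and only slightly in an added one. Over the tested probe sets the mean correlation was 0.925 between arrays of the same treatment and 0.923 between arrays of different treatments, a difference of 0.00256 (exact permutation test, one-sided, p = 0.1995). Against divisions within the replicate ranges alone, a test added after the ranges had been noticed, the same difference passed (exact permutation test, one-sided, 5040 divisions, p = 0.0405). Arrays of the same replicate range correlated at 0.935 and those of different ranges at 0.913.

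RNA quality was compared through the control probe sets at the 3' and 5' ends of beta-actin and GAPDH transcripts. The log2 ratio of 3' over 5' was 1.09 ± 1.39 in DMSO arrays and 0.69 ± 0.33 in mefloquine arrays for beta-actin (SD, n = 8 each; exact permutation p = 0.672), and 0.54 ± 0.69 and 0.30 ± 0.16 for GAPDH (SD, n = 8 each; exact permutation p = 0.494). DMSO control 3 had ratios of 21.3 and 4.62, while those of the other arrays lay between 1.31 and 2.67 for beta-actin and between 1.02 and 1.48 for GAPDH. Without this array the DMSO means were 0.61 ± 0.36 and 0.30 ± 0.14 (SD, n = 7), and the differences, mefloquine minus DMSO, were 0.08 and -0.00 instead of -0.40 and -0.24 (exact permutation p = 0.652 and 0.994).

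**Figure D3:**
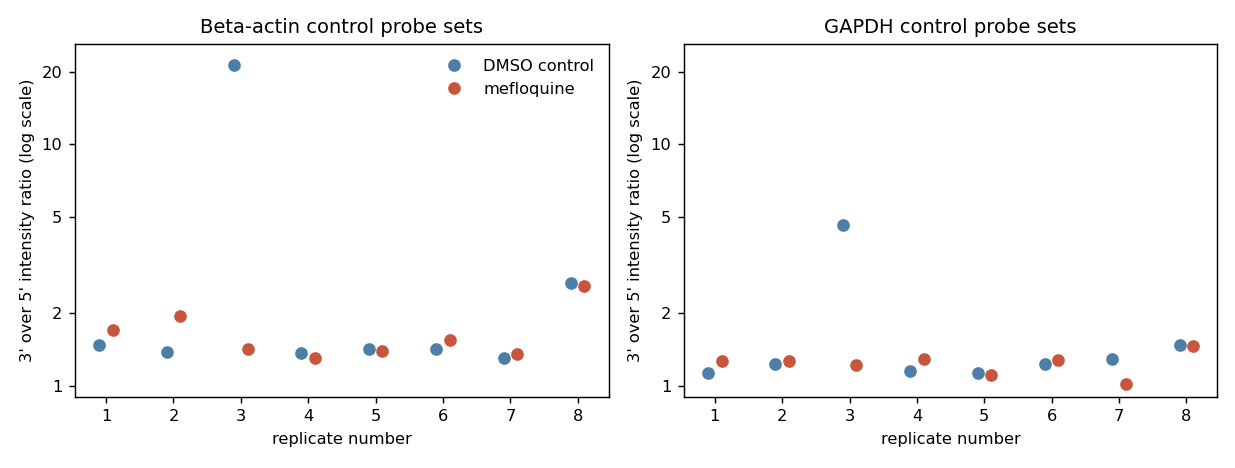
Ratio of 3' over 5' intensity (vertical axes, log scale) of the beta-actin and GAPDH control probe sets on each array, by replicate number, with DMSO control in blue and mefloquine in red. DMSO control 3 stands at 21.3 and 4.62, above all other arrays.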

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

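The search for arrays far from the rest of their group was set in advance, whereas all tests of explanations in this part were chosen after the results had been seen. Within each group of 8 arrays, the highest or lowest value of each named gene, each other called probe set and each quality measure was compared with its nearest neighbour by Dixon's test. Of 124 such tests 19 stood out (15.3%), where chance gives about 5%, and 15 of the 19 concerned DMSO control 3. None of the 59 control probe sets differed between the treatments (exact permutation tests, lowest p = 0.0976 unadjusted; 0 under 0.05).

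DMSO control 3 lay above the other 7 DMSO arrays, on the log2 scale, for Ddit3 at 10.72 (others 8.74 to 9.57), Canx at 15.59, Hspd1 at 15.72 and Cox4i1 at 16.43. It lay below them for Hspa8 at 14.72, Creb1 at 9.13, Clu at 10.08, Cyp51 at 9.33, Atp1b3 at 10.82, and, at the floor of 8.74, for Hmox1 (8.736), Atp1b2 (8.736) and AA956437_at (8.736). Its log2 ratios of 3' over 5' were 4.42 for beta-actin and 2.21 for GAPDH, and its median correlation with the other arrays was 0.855 (other DMSO arrays 0.925 to 0.945, mefloquine 1 and 2 at 0.9008 and 0.9125). On other arrays, Kcnj8 was high on mefloquine 1 (9.99), Vegfa was at the floor on DMSO control 2 (8.736), Ccne1 was low on mefloquine 2 (9.82), and the dimmest Jun probe set was high on DMSO control 4 (9.68).

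The values of DMSO control 3 are consistent with shortened RNA, since its beta-actin ratio was 21.34 where the highest of the other arrays was 2.67, and its GAPDH ratio of 4.62 compares with 1.48. Strong spike-in signal over a dim sample could not be separated from this. The other 2 arrays with the strongest spike-ins, mefloquine 1 and 2, had beta-actin ratios of 1.70 and 1.95, far below 21.34. Next in spike-in signal were the arrays of replicate 8, with ratios of 2.58 and 2.67. All arrays with weaker spike-ins were at 1.55 or below, so the ratio was higher where spike-ins were strong. No biological explanation was tested, as the labels give this sample no condition of its own. Whether its RNA was in fact shortened was not measured in another way, and the reason for its high ratios stays open.

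The rise of Ddit3, Jun and Nfkbia might come from uneven RNA quality, from scaling or from chance. With the GAPDH ratio as a covariate each gene kept at least 91.1% of its log2 difference, and without DMSO control 3 at least 92.4%. That array dominates the ratio, so these figures are close to a single test. Without it and mefloquine 1 and 2 the log2 differences were 2.38 for Ddit3, 1.7 for Jun and 1.31 for Nfkbia. A scaling offset would have moved all probe sets, whose median difference was -0.0139. The deposited values were already scaled by chip, so a median near 0 was likely in advance and decides little about scaling. Among 100 divisions of the arrays into 8 and 8, 2 called at least 7 probe sets, the real one with 7 and another with 40, which put all 6 arrays of replicates 6 to 8 on one side and so followed that structure. With the replicate range as a block the real division called 8, the highest other called 1, and only the real one of 100 reached 8, so chance is argued against in both. An effect of mefloquine stays as the hypothesis that the design names, on arrays whose independence is not stated. The labels also do not say whether the mefloquine samples contained DMSO, so a difference in DMSO cannot be told apart from the drug.

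The arrays of replicates 6 to 8 differed from those of replicates 1 to 5 by 68 probe sets, 12 higher and 56 lower, and by 112 without the 3 arrays that stood apart. RNA quality is argued against as the whole cause, since there 60 probe sets differed with the beta-actin ratio as a covariate and 88 with the GAPDH ratio. These are fresh counts, not matched to the 112, and 60 is just over a bound set afterwards. Without replicate 8 as well, the counts were 60 with no covariate, 55 with beta-actin and 66 with GAPDH. RNA quality may account for a part through replicate 8. Without it the beta-actin difference between the ranges fell from 0.31 (log2, exact permutation p = 0.0944, n = 6 and 7) to 0.01 (p = 0.77, n = 4 and 7), though fewer arrays also lower the count. A condition shared by both groups stays open, because the ranges were noticed on these arrays. Replicates 6 to 8 ranked 2 of 56 trios in mefloquine arrays but 15 in DMSO arrays. The top DMSO trio, 2, 3 and 5, holds DMSO control 3 and ranked 28 in mefloquine arrays. The trios were not ranked without that array, so the ranks decide little. The 5S ribosomal RNA control probe set, also seen on these arrays, goes with a shared condition. Over both groups it was at 2591 to 4370 in replicates 6 to 8 and at -915 to 2475 in replicates 1 to 5. The labels name no such condition, no biological explanation was tested, and both groups hold both ranges equally, so the treatment comparison is not confounded with them.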

How the results depend on the processing

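The batch block, the single replicate ranges and the fit without 3 arrays were chosen after the data had been seen; the other settings were planned. The 7 changed probe sets (6 higher, 1 lower) became 4 with quantile normalization, with a floor at the 10th or 40th percentile and with an offset, each time with 0 lower, and the 4 were the same: Ddit3, both Nfkbia probe sets and the brightest of Jun. With all 16 arrays above the floor, where Ddit3 is not tested, 3 changed, 3 were higher, 0 lower and 3 at least 2-fold. Leaving out 1 array at a time gave 4 to 8 changed and 0 to 1 lower; the count was 4 without DMSO control 2, 6, 7 or 8 or mefloquine 3 or 4. In replicates 1 to 5 alone 6 changed, 0 of them lower. In replicates 6 to 8 alone, with 3 arrays per group, 1 changed, which was higher and at least 2-fold, and 0 were lower. Without the 3 arrays that stood apart 5 changed, and with the batch block 8. The count of changed gene lists, 0, became 1 (immediate early genes) with a floor at the 40th percentile, with all 16 arrays above the floor and with all probe sets; with an estimated correlation none of these calls held (adjusted p 0.337, 0.19 and 0.105), nor without Jun. Fewer probe sets or arrays were tested under the filter and the single ranges; otherwise the cause was not tested. The replicate block gave 8 changed, the 7 and Junb; the numbers were not taken as pairs, as the rule asked for a correlation above 0.1 in all 8 cases. It was above in 7 (0.0569 to 0.593, with 0.447 or more for numbers 5 to 8; median of other pairs -0.133), so some shared condition stays possible, and only 2 DMSO arrays correlated best with their own number. Junb also passed with median scaling, both batch blocks and without mefloquine 8 (adjusted p 0.0282 to 0.691 over all settings), and Hmox1 with the weighted batch block (0.0329 to 0.99). No called result changed direction, and the array separation (0.00256) passed only against divisions within the replicate ranges, an added exact permutation test (p = 0.0405). The 51 named genes kept their sign under both scalings, but 25 of them, none called, turned in sign under some alternative, 14 in replicates 6 to 8 alone. Dim probe sets are limited by the floor: 427 of 972 were not tested.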

Other observations

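All tests in this part were chosen after the results had been seen, and the 4 gene lists below were put together from the array's content at that stage. Among 37 tested genes of the mitochondrial respiratory chain, 0 passed limma's test, 29 lay below 0 with mefloquine and 8 above, and the median log2 difference was -0.10. DMSO control 3 was far above the other DMSO arrays for Cox4i1, and without it the median was -0.06, with 27 below 0, against -0.05 over all genes. Without the 3 arrays that stood apart 18 lay below 0 and 19 above. Among 21 cytochrome P450 enzymes 0 passed and the median was -0.05 (limma camera, adjusted p = 0.271; p = 0.383 with an estimated correlation). The 15 genes of DNA replication and repair also gave 0, with 12 below 0 and a median of -0.09 (limma camera, adjusted p = 0.166; p = 0.101 with an estimated correlation). The 14 peptidyl-prolyl isomerases and co-chaperones gave 0 and a median of 0.01 (limma camera, adjusted p = 0.323; p = 0.312 with an estimated correlation). Of the P450 enzymes, Cyp3a23-3a1, a drug-metabolising enzyme of the liver, was 2.00-fold higher at intensities of 678 and 1442 (log2 1.00 ± 0.30 SE; limma adjusted p = 0.214), with 3 DMSO arrays at the floor, and it passed in replicates 1 to 5 alone at a log2 difference of 1.46. X62086mRNA_s_at, which carries several symbols, differed by -0.27, and Cyp2b1, the P450 gene with the next smallest p, by -0.68 ± 0.25 by L00320cds_f_at (limma adjusted p = 0.551) and by 0.10 by M11251cds_f_at.

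A joint fall of the respiratory chain genes was tested as a hypothesis. Camera gave an adjusted p of 0.0943 over the 4 lists in limma, with p = 0.271 at an estimated correlation and 0.761 when DMSO control 3 was also left out. Without the 3 arrays that stood apart the list's median was 0.003, against -0.043 over all genes, so no lean below 0 remained. These data neither show nor exclude a joint fall, and the lean rests largely on the arrays that stood apart. Genes of this list vary together between arrays, with an estimated correlation between genes of 0.131.

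A rise of the other measured members of the endoplasmic reticulum list as large as that of Ddit3 was tested as another hypothesis. The values argue against it for the 9 members measured, while only 10 of the list's 27 genes have a probe set of their own. Ddit3 was singled out as the largest rise among the called genes of these same data, which favours this outcome. The 95% intervals of all 9 other tested members lay wholly below that of Ddit3, whose lower limit was 1.67 on the log2 scale. This comparison replaced an earlier one, whether each member's interval excluded a 2-fold rise, which had left the question open. The highest of their upper limits was 1.28, for Hsp90b1, and their median difference was -0.03. Smaller rises stay open, since on the floored scale a 2-fold rise was excluded for 7 of the 9.

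The 5S ribosomal RNA control probe set was higher by 2767 intensity units in replicates 6 to 8 than in replicates 1 to 5, with the 3 arrays that stood apart left out (exact permutation test, n = 6 and 7, p = 0.000583). In the same comparison the spike-in mean was higher by 0.46 (log2, p = 0.035), the beta-actin ratio by 0.31 (p = 0.0944) and the GAPDH ratio by 0.12 (p = 0.156), each by the exact permutation test and unadjusted. Without replicate 8 as well, 5S was higher by 3023 units (exact permutation test, n = 4 and 7, p = 0.00303), the spike-in mean by 0.25 (p = 0.182), the beta-actin ratio by 0.01 (p = 0.77) and the GAPDH ratio by 0.02 (p = 0.73).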
